A study of Mus musculus with 6 samples.

How the data were processed

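Total RNA of sorted mammary basal cells was sequenced in 6 libraries, 3 GFPpos and 3 GFPneg. Groups and replicate numbers came from the sample labels. The authors deposited whole-number counts per gene symbol for each library (51826 symbols and 5 summary rows). Per the submitters' processing notes, FastQC, cutadapt, TopHat2 and HTSeq were used with genome build mm10. Tool versions, counting mode, strand setting and annotation release are not given in the sources used here, so that overlapping, antisense and near-identical genes are uncertain. The deposited counts hold 0 reads in the row for more than 1 alignment. How such reads were handled is not given, so that counts of genes that share sequence with copies are uncertain. Gene positions were taken from GENCODE M21 on the same assembly, in which 47523 symbols had 1 position.

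The summary rows were left out of library sizes and tests. Reads assigned to no feature made up 66.4% of all assigned and unassigned rows in GFPneg replicate 1 and 28.8% to 40.5% in the other libraries, and ambiguous reads 0.390% to 2.07%. Of the 5 abundant noncoding features, Gm26917 (chromosome 17, 39843013 to 39846341) and Gm42418 (chromosome 17, 39846958 to 39848788) are annotated as lincRNA, Gm23935 (chromosome 16, 11144125 to 11144181) as miRNA, and mt-Rnr1 and mt-Rnr2 as mitochondrial rRNA. Intervals for ratios of low counts are 95% exact and cover counting error only.

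Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr by group, group as the only term), which left 13873 genes, or 15274 without GFPneg replicate 1. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. CPM values were divided by the effective library size (TMM factor 0.501 for GFPneg replicate 1 and 1.05 to 1.22 for the others). The SE of a log2 fold change was its unshrunk value divided by the square root of F. Of 28 gene lists, 25 had at least 5 measured members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and also with an estimated correlation and with fry. Immune cell, red blood cell and skeletal muscle markers had fewer (4, 0 and 2 tested). The lists, the main test and most of the other settings were fixed before the data were examined.

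The rule for named genes took 18 fixed genes, up to 8 genes with the largest change in each direction (adjusted p below 0.05, at least 5 CPM in the higher group, 1 direction in all 3 pairs, no predicted or clone names) and up to 4 members with the smallest p of each list. Other genes are named only in the closing section, as chosen after their values were seen. The values of some genes that the rule takes are not reported here.

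The design states that both fractions of a replicate came from the same pool, so the replicate number pairs the samples. The deviations of the 2 fractions of a pair from their group means correlated at -0.036, 0.122 and -0.0013 for replicates 1, 2 and 3. A fit with the replicate block was also made. The further settings were DESeq2 1.42.0 (with and without the block), limma-voom, other scaling and filters, a test against a log2 change of 1, and leaving out each library and each pair. Removal of the 5 features, the block without replicate 1, and sample quality weights were added after the data were seen. The block without replicate 1 holds only 2 pairs and leaves few residual degrees of freedom. Its p-values rest largely on the spread that edgeR shares across genes, so that small ones do not stand for strong replication.

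The scripts were tested on simulated data with 200 changed genes among 13873, drawn with the pooled gene means and the sizes of the 6 libraries. The changed genes were taken from the more abundant genes only. The draws held no pair effect and no library with a profile of its own. The rates below therefore do not cover genes of low level or a library that differs as GFPneg replicate 1 does. The test without a block recovered 0% of genes changed by 1 on the log2 scale, 19.4% by 2 and 92.4% by 4, with 4 genes called falsely. With the block it recovered 0%, 14.9% and 89.4% and called 3 falsely. Camera with the preset correlation called 3 of 3 shifted lists and 0 others. Correlation between genes was not taken from the data for these draws. The camera result therefore cannot show how the preset performs on lists whose genes move together. In the real data the estimated correlation of the tested lists ranged from -0.124 (milk and alveolar genes) to 0.701 (mitotic genes). With an estimated correlation camera also tests on the few residual degrees of freedom of the fit, so that p can rise whatever the correlation. For fibroblast markers the estimate (-0.00955) lay below the preset, and camera's adjusted p was 0.216 against 2.66e-05 with the preset. The mice of a replicate were pooled, so that spread between libraries is spread between pools.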

Results

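RNA-seq was performed on mammary basal cells sorted from pubertal mice of the SMAcreERT2/N1ICD genotype, in which a tamoxifen-inducible Cre recombinase under a smooth muscle actin promoter is combined with an allele for the intracellular domain of Notch1, the active form of this receptor. Tamoxifen was given once at postnatal day 21 and cells were isolated 72 hours later, at day 24. GFP-positive (GFPpos) and GFP-negative (GFPneg) cells were sorted from each of 3 pools of 2 to 3 mice, giving 3 libraries per group and 6 in all. The series title states its question as the change of cell fate that Notch activation induces in mammary cells, and the comparison of GFPpos with GFPneg cells bears on it. All 6 libraries came from mice of this genotype, with none of labelled cells that lack the allele. A change of fate therefore cannot be told apart from a difference in which cells became GFP-positive.

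The libraries differed in depth. GFPneg replicate 1 held 611465 gene counts over 7454 genes, and the other 5 libraries held between 9912610 (GFPneg replicate 3) and 16043492 (GFPneg replicate 2). GFPpos replicates 1, 2 and 3 held 10549065, 11272213 and 15825199. In GFPneg replicate 1, 69.2% of the gene counts lay in 5 abundant noncoding features (Gm23935, Gm26917, Gm42418, mt-Rnr1 and mt-Rnr2), against 22.7% to 34.7% in the others, which left 188291 counts for all other genes. A single count in that library equalled 3.28 CPM (counts scaled to the library size), and 0.0513 to 0.0911 CPM in the others. Its correlation with each other library (Pearson's r across genes, which are not independent replicates) lay between 0.616 and 0.651, and those among the other 5 libraries between 0.803 and 0.928.

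**Figure D1:**
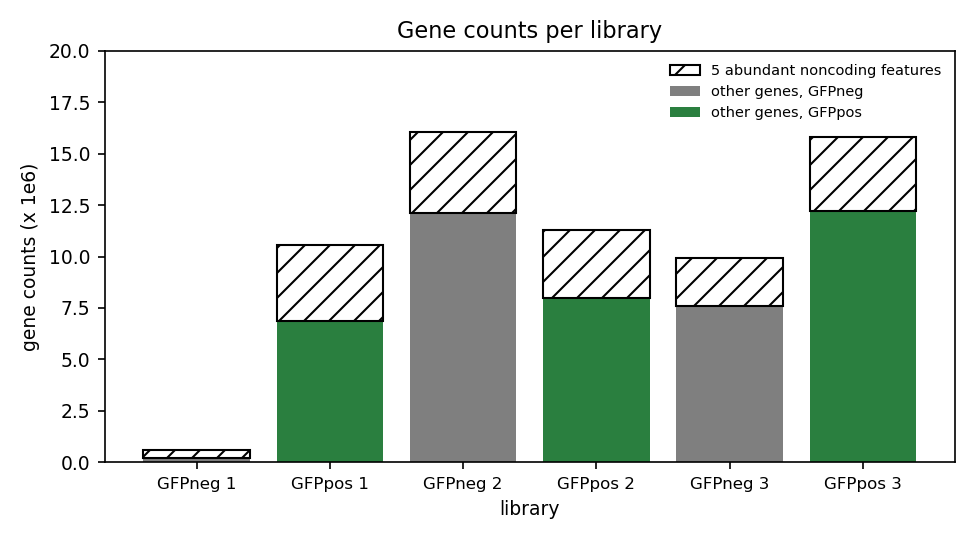
Gene counts per library (bars from 0, axis in units of 1e+06), with counts in the 5 abundant noncoding features hatched and counts in all other genes filled by group. GFPneg replicate 1 holds 611465 gene counts, and the other 5 libraries hold 9912610 or more.

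Reads of Notch1, the gene whose intracellular domain the allele carries, were more numerous in GFPpos cells of each of the 3 pairs, at 463 ± 41.7 CPM (SD, n = 3) against 183 ± 81.4 CPM in GFPneg cells (chromosome 2, 26457903 to 26516663, mm10). The log2 fold change was 1.32 (SE 0.41), which did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.625). Notch1 passed in that test with the replicate block without replicate 1 (adjusted p = 0.0350), a fit of 2 pairs chosen after the data were seen. Counts from the allele and from the endogenous gene were not separated.

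GFPpos cells expressed more Ccnd1, which encodes the cell cycle regulator cyclin D1, at 443 ± 27.5 CPM against 53.5 ± 23.5 CPM in GFPneg cells (SD, n = 3), 8.54-fold higher. Fbn2, which encodes the extracellular matrix protein fibrillin-2, stood at 451 ± 237 against 7.66 ± 9.20 CPM, and the chemokine gene Ccl21a at 290 ± 74.0 against 8.30 ± 5.99 CPM. The sulfotransferase gene Chst4 (106 ± 84.4 against 1.26 ± 1.76 CPM) and Madcam1, which encodes an adhesion molecule bound by lymphocytes, were close to absent from GFPneg cells. Madcam1 had 848 counts in the GFPpos libraries and 1 in the GFPneg libraries, a ratio of 604 after scaling to library size (95% interval 108 to 23904, counting error only). The remaining genes that rose were Serpina1e, Serpinb9 and Clu, and the 1 gene that fell was Krt1, a keratin of differentiating epidermis, with 3 counts in GFPpos and 1507 in GFPneg libraries, a GFPneg to GFPpos ratio of 705 (241 to 3421).

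In total 8 genes were higher and 1 was lower in GFPpos cells among 13873 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), each in the same direction in all 3 pairs, and 330 were higher and 400 lower at an unadjusted p below 0.05. Log2 fold changes were 5.53 (SE 0.72, adjusted p = 0.00637) for Fbn2, 5.41 (SE 0.71, adjusted p = 0.00637) for Ccl21a, 3.09 (SE 0.46, adjusted p = 0.0181) for Ccnd1 and 3.24 (SE 0.50, adjusted p = 0.0197) for Clu. With the replicate number as a block, 43 genes were higher and 18 lower, and all 9 genes above were among them. The counts moved with single libraries. They were 63 higher and 29 lower without GFPneg replicate 1, 3 and 3 without GFPneg replicate 2, 8 and 11 without GFPneg replicate 3, 5 and 1 without GFPpos replicate 1, 7 and 4 without GFPpos replicate 2, and 2 and 1 without GFPpos replicate 3. All 9 genes were called without GFPneg replicate 1, and 3 of them (Fbn2, Ccl21a and Krt1) without GFPneg replicate 2 or without GFPpos replicate 3. Madcam1, Serpina1e and Serpinb9 were lost without GFPpos replicate 1 or without GFPneg replicate 3, and Madcam1 alone without GFPpos replicate 2, so that Madcam1 was called in 1 of the 6 fits without a single library.

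**Figure D2:**
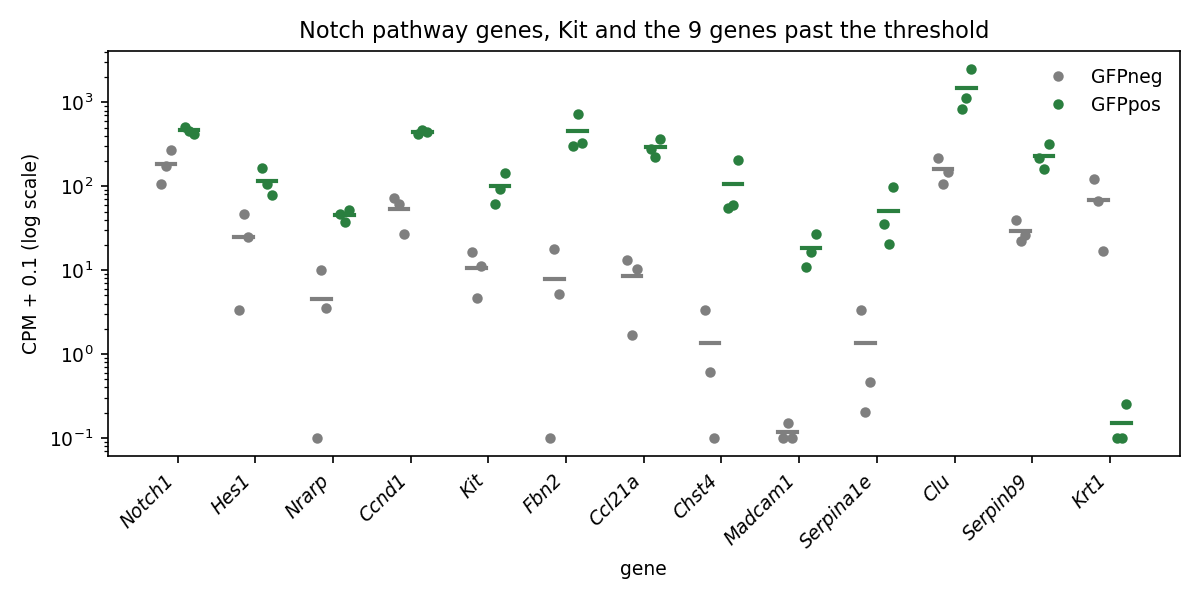
CPM plus 0.1 on a log axis for 13 genes in the 3 GFPneg (grey) and 3 GFPpos (green) libraries, with points for libraries and bars for group means. Ccnd1 averages 443 CPM in GFPpos and 53.5 CPM in GFPneg libraries, and Krt1 has 3 counts over the GFPpos libraries.

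Genes known as targets of Notch signalling were shifted up as a list. Of 12 measured members, 9 had positive fold changes with a median log2 value of 1.01, 1 rose in the test over all genes (Ccnd1) and 4 rose adjusted over the list alone (camera, adjusted p = 0.00269 with a preset correlation, adjusted p = 0.321 with an estimated correlation). Hes1, a transcriptional repressor, averaged 116 ± 44.2 CPM in GFPpos and 25.0 ± 21.9 CPM in GFPneg cells, and Nrarp, a feedback regulator of the pathway, 45.1 ± 7.09 and 4.46 ± 5.03 CPM (n = 3 each). The receptor gene Notch3 averaged 178 ± 91.3 and 41.9 ± 19.9 CPM, Heyl 25.2 ± 15.2 and 6.78 ± 7.80 CPM, and Hey1 17.4 ± 13.4 and 13.8 ± 8.82 CPM. None of these 5 genes passed edgeR's threshold over all genes with the 6 libraries. Nrarp passed with DESeq2 (adjusted p = 0.0130), with DESeq2 and the replicate block (0.0212), with no low count filter (0.0349) and without GFPneg replicate 1 (0.0400). Notch3 passed with no low count filter (0.0103), with DESeq2 and the replicate block (0.0241) and with limma-voom (0.0431), and Hes1 with no low count filter (0.0343). The replicate block without replicate 1 rests on 2 pairs and was chosen after the data were seen. That fit called Nrarp (1.51e-05), Notch3 (2.54e-08) and Hes1 (0.00399), and not Heyl (0.0750) or Hey1 (0.458). The list was not called without GFPneg replicate 2 (adjusted p = 0.0861). Notch3 and Heyl are also members of the pericyte list, which was shifted up too.

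Cell cycle genes were shifted up together. Of 30 mitotic genes, 29 had positive fold changes (median log2 2.02), 0 rose in edgeR's test over all genes and 10 rose adjusted over the list alone (camera, adjusted p = 2.52e-23, and adjusted p = 0.321 with an estimated correlation). Of 32 DNA replication genes, 28 were positive (median 1.19), and 0 rose in either count (adjusted p = 5.62e-07, and adjusted p = 0.321 with an estimated correlation). The proliferation marker Mki67 averaged 846 ± 254 CPM in GFPpos and 206 ± 171 CPM in GFPneg cells, Cenpf, a kinetochore gene, 220 ± 80.6 and 29.6 ± 38.7 CPM, and the helicase subunit gene Mcm3 95.9 ± 9.16 and 34.8 ± 21 CPM. With the replicate block, 4 mitotic genes rose, among them Mki67 (adjusted p = 0.000896) and Cenpf (adjusted p = 3.23e-05), and 0 DNA replication genes. The block without replicate 1, chosen after the data were seen, called 23 mitotic and 6 DNA replication genes higher. Both lists were called in each fit that left out a library or a pair.

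Lists of genes of the basal layer and of the matrix it rests on were called down over the 3 pairs, while their replicate 1 pair went the other way. Of 28 basal keratin, adhesion and transcription factor genes, 25 had negative fold changes (median log2 -0.47). Of these, 0 fell in edgeR's test over all genes and 2 fell adjusted over the list alone (camera, adjusted p = 1.19e-05, and adjusted p = 0.340 with an estimated correlation). Col17a1, which encodes a hemidesmosomal collagen, averaged 512 ± 129 CPM in GFPpos and 1432 ± 146 CPM in GFPneg cells, and the Wnt inhibitor gene Wif1 5.66 ± 2.32 and 41.0 ± 24.6 CPM, and both fell without GFPneg replicate 1 (adjusted p = 0.0328 and 0.00631). The basal keratin genes Krt5 (976 ± 231 against 1399 ± 361 CPM) and Krt14 (1015 ± 330 against 1818 ± 206 CPM) and the transcription factor gene Trp63 (157 ± 39.1 against 241 ± 66.3 CPM) were lower in GFPpos cells of all 3 pairs and did not pass the threshold in any leave-out fit of edgeR. Basement membrane and hemidesmosome genes (26 of 29 negative, median -0.66, 1 lower adjusted over the list alone) had an adjusted p of 2.90e-08, and 0.321 with an estimated correlation. Wnt pathway genes (21 of 30 negative, median -0.44, 2 lower adjusted over the list alone) had an adjusted p of 0.000117, and 0.321 with an estimated correlation. By pair, the median log2 ratio of CPM + 1 in replicates 1, 2 and 3 was 0.21, -0.62 and -0.85 for the basal list, 0.15, -0.63 and -1.10 for the basement membrane list and 0.61, -0.41 and -0.80 for the Wnt list.

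Smooth muscle contractile genes did not pass as a list (16 of 23 negative, median log2 -0.33, camera adjusted p = 0.0730), and were shifted down without GFPneg replicate 1 (adjusted p = 2.46e-06, and adjusted p = 0.182 with an estimated correlation). Acta2, which encodes smooth muscle actin, averaged 1283 ± 124 CPM in GFPpos and 2069 ± 1641 CPM in GFPneg cells. It was higher in GFPpos cells in replicate 1 (1380 against 367 CPM) and lower in the other pairs. Its log2 fold change ranged from -1.22 to -0.0021 over the fits that left out a library or a pair. With the replicate block without replicate 1 edgeR called Acta2 lower (log2 -1.18, adjusted p = 0.0304). The pair medians of the list were 1.00, -0.61 and -0.48. Cnn1, which encodes calponin, averaged 96.9 ± 14.1 and 266 ± 44.7 CPM, and fell without GFPneg replicate 1 (adjusted p = 0.0158).

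Luminal epithelial genes were called up as a list, with most of the difference in replicate 1. Of 29 luminal epithelial genes, 23 had positive fold changes (median log2 0.43), and 0 rose in edgeR's test over all genes or over the list alone (camera, adjusted p = 0.0369, and adjusted p = 0.624 with an estimated correlation). The pair medians were 1.74, 0.16 and -0.12 in replicates 1, 2 and 3. Lists that were not called also had high replicate 1 medians, such as 1.15 for p53 targets and 1.00 for interferon response genes. Major histocompatibility class I genes (-0.50) and endothelial markers (-0.51) were negative there. The replicate 1 difference is therefore not shown to be particular to luminal genes. The median log2 fold change of the luminal list was 0.27 without GFPneg replicate 1. The call was lost with the replicate block (adjusted p = 0.104) and without GFPneg replicate 1 (0.0983), GFPpos replicate 1 (0.163), GFPneg replicate 2 (0.0730) or GFPpos replicate 2 (0.111). The keratin genes Krt8 (122 ± 22.1 against 83.8 ± 33.4 CPM), Krt18 (151 ± 68.0 against 87.4 ± 19.7 CPM) and Krt19 (91.3 ± 31.9 against 18.1 ± 19.8 CPM) did not pass the threshold, and Krt19 did with no low count filter (adjusted p = 0.0464). Krt19 also passed with the replicate block without replicate 1 (adjusted p = 0.000136), and Krt8 (0.996) and Krt18 (0.967) did not. Kit, a receptor of luminal progenitors, averaged 99.6 ± 42.1 CPM in GFPpos and 10.6 ± 5.95 CPM in GFPneg cells (adjusted p = 0.0891). It rose with the replicate block (adjusted p = 0.00358) and without GFPneg replicate 1 (adjusted p = 0.00523). The hormone receptor genes Esr1 (13.9 ± 2.20 against 4.06 ± 6.49 CPM) and Pgr (18.9 ± 17.6 against 11.2 ± 9.75 CPM) and the transcription factor genes Gata3 (62.3 ± 25.7 against 94.1 ± 42.1 CPM), Foxa1 (2.20 ± 0.856 against 3.09 ± 3.10 CPM) and Elf5 (1.25 ± 0.911 against 1.00 ± 1.36 CPM) did not pass either.

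Markers of other cell types also moved with the groups. Pericyte and vascular smooth muscle markers were shifted up (10 of 11 positive, median log2 1.65, camera adjusted p = 1.52e-05, and adjusted p = 0.340 with an estimated correlation). Fibroblast markers were shifted down (10 of 14 negative, median -1.13, adjusted p = 2.66e-05, and adjusted p = 0.216 with an estimated correlation). Postn, a member, averaged 268 ± 63.6 CPM in GFPpos and 974 ± 604 CPM in GFPneg cells (adjusted p = 0.396), and its replicate 1 pair did not fall (324 against 302 CPM). It fell without GFPneg replicate 1 (adjusted p = 0.00378). Schwann cell and neural markers were shifted down (5 of 8 negative, median -1.31, adjusted p = 0.00368, and adjusted p = 0.340 with an estimated correlation), and were not called without GFPneg replicate 3 (adjusted p = 0.106). Their pair medians were 0.71, -0.56 and -2.05. In edgeR's test over all genes 0 members of these 3 lists passed, and adjusted over the list alone 1 pericyte marker was higher and 1 fibroblast and 2 Schwann cell markers were lower. Endothelial markers were not called (10 of 19 positive, median 0.03, mean -0.20, adjusted p = 0.398). They were called down without GFPpos replicate 3 (adjusted p = 0.00569, and 0.538 with an estimated correlation) or without both libraries of replicate 3 (adjusted p = 0.000364, and 0.675 with an estimated correlation). Their median level was 99.3 CPM in GFPpos replicate 3, against 38.8 and 42.9 CPM in the other GFPpos libraries, and 88.5, 41.8 and 42.1 CPM in GFPneg replicates 1, 2 and 3. Glycam1, a mucin gene of milk and of lymph node venules, averaged 9469 ± 3905 CPM in GFPpos and 906 ± 1285 CPM in GFPneg cells (adjusted p = 0.493), and rose with the replicate block (adjusted p = 2.41e-16) and without GFPneg replicate 1 (adjusted p = 0.0122). Its level was 2380, 25.2 and 312 CPM in GFPneg replicates 1, 2 and 3.

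Immediate early and dissociation stress genes were shifted down (25 of 28 negative, median log2 -0.37, camera adjusted p = 6.43e-05, and adjusted p = 0.348 with an estimated correlation), as were YAP target genes (13 of 18 negative, median -0.19, adjusted p = 0.0241, and adjusted p = 0.614 with an estimated correlation). TGF-beta and BMP response genes were called down (adjusted p = 0.0369, and adjusted p = 0.614 with an estimated correlation) with a median of 0.01 and a mean of -0.32. The YAP call was lost without GFPpos replicate 1 (adjusted p = 0.0794), GFPneg replicate 2 (0.110), GFPpos replicate 2 (0.133) or GFPneg replicate 3 (0.228), and the TGF-beta call without any 1 library other than GFPneg replicate 1 (0.0816 to 0.134). Both were also lost with library size only (0.125 for YAP and 0.136 for TGF-beta) and with no low count filter (0.262 and 0.412). In these 3 lists 0 genes passed edgeR's test over all genes. In each the replicate 1 pair went the other way. The pair medians were 0.23, -0.72 and -0.65 for the immediate early list, 0.79, -0.63 and -0.76 for the YAP list and 0.26, -0.53 and -0.10 for the TGF-beta list. The other tested lists were not called. Their adjusted p was 0.0730 for estrogen receptor negative luminal progenitor genes and for major histocompatibility class I genes, 0.114 for Notch receptors, ligands and cofactors, 0.454 for cholesterol synthesis, 0.646 for adipocyte markers, 0.647 for hormone receptor positive luminal genes, 0.903 for interferon response, 0.914 for milk and alveolar genes, 0.927 for epithelial-mesenchymal transition regulators and 0.989 for p53 targets. The medians of the milk (-0.02) and transition (-0.06) lists had the opposite sign to their means (0.15 and 0.16). Without GFPneg replicate 1, major histocompatibility class I genes (2.64e-07, and adjusted p = 0.282 with an estimated correlation) and immune cell markers (9 tested, 0.00247, and adjusted p = 0.437 with an estimated correlation) were also called up. The class I list was called up as well with library size only (adjusted p = 0.0120), with no low count filter (0.00377), without GFPpos replicate 1 (0.0286) and without GFPpos replicate 2 (0.0360). The estrogen receptor negative progenitor list was called up with no low count filter (0.0339) and without GFPpos replicate 3 (0.00787), and interferon response genes were called down without both libraries of replicate 3 (0.049995). The immune markers were called up with no low count filter (0.0234) and without GFPpos replicate 1 (0.000332). With an estimated correlation 0 of these calls stayed (adjusted p of 0.282 or more).

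**Figure D3:**
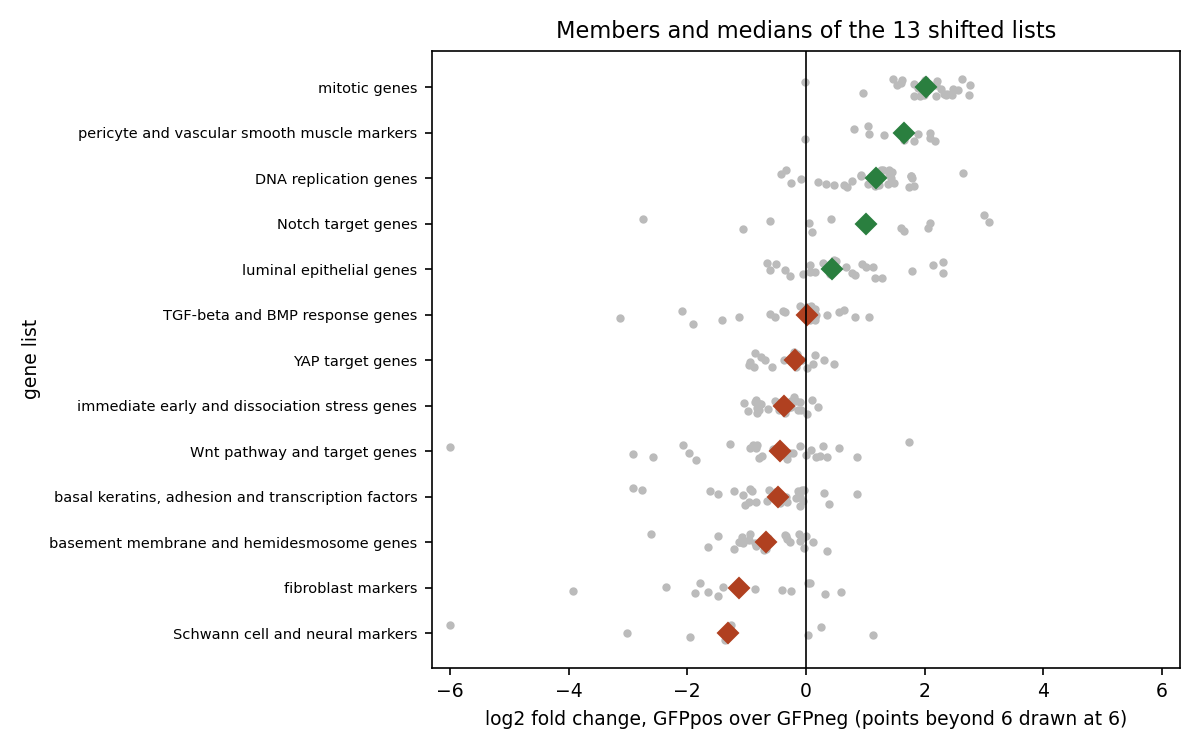
Log2 fold changes (GFPpos over GFPneg) of the measured members of the 13 shifted gene lists, with grey points for genes (beyond 6 drawn at 6) and diamonds for list medians (green up, red down by camera). The mitotic genes have a median of 2.02 and the basement membrane genes one of -0.66, and 0 of the 13 calls held with an estimated correlation.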

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

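The 8 higher and 1 lower genes (13873 tested) became 43 and 18 with the replicate block, 63 and 29 without GFPneg replicate 1, 65 and 236 with no low count filter, 51 and 104 with DESeq2, 77 and 90 with DESeq2 and the replicate block, and 54 and 24 with limma-voom. They became 5 and 1 with library size only, and 3 and 1 in the test against a log2 change of 1. Of the alternatives chosen after seeing the data, the replicate block without replicate 1 (2 pairs) gave 386 and 216 and sample quality weights 46 and 26. Removing the 5 noncoding features gave 8 and 1. Over the fits that left out a library or a pair, the count of higher genes ranged from 2 to 63 and that of lower genes from 1 to 68. All 9 genes were called with the block, with DESeq2, with the other filters and without GFPneg replicate 1. Library size only lost Ccnd1, Madcam1 and Serpinb9, limma-voom Madcam1, and quality weights Madcam1 and Serpina1e. Genes given in the results that edgeR did not call with the 6 libraries passed with no filter (Hes1, Nrarp, Notch3, Krt19, Kit, Col17a1, Wif1, Glycam1, Mki67, Cenpf and Postn), DESeq2 (Nrarp, Kit, Wif1 and Cenpf), DESeq2 and the block (the same 4, and Notch3, Glycam1 and Mki67), limma-voom (Notch3, Kit, Col17a1, Wif1, Cnn1, Glycam1, Mki67 and Postn) and quality weights (Notch1, Kit, Col17a1, Wif1, Cnn1, Glycam1 and Postn). The replicate block without replicate 1 called Notch1, Hes1, Nrarp, Notch3, Krt19, Kit, Col17a1, Wif1, Cnn1, Acta2, Glycam1, Mki67, Cenpf, Mcm3 and Postn. Without GFPneg replicate 1, Nrarp, Kit, Col17a1, Wif1, Cnn1, Glycam1 and Postn passed, and with the replicate block Kit, Glycam1, Mki67 and Cenpf. The cause of the other changes was not tested. The lists shifted up (5) and down (8) were 0 and 0 with an estimated correlation, in each of the edgeR fits (lowest adjusted p = 0.172), and 0 and 0 with fry, 8 and 6 with no low count filter, and 3 to 6 and 5 to 9 over the leave-out fits. The loss with an estimated correlation does not show that correlation between genes made the calls, since that setting also tests on few degrees of freedom. The replicate block gave 4 and 8, losing the luminal epithelial list, and changed no other list call. The median log2 fold change of all tested genes was 0.15, 0.31 with library size only, 0.32 with the replicate block and -0.20 with DESeq2, and values near 0 move by as much.

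Directions that reversed all belonged to genes that did not pass the threshold. Elf5 (-0.02) was 0.10 with the replicate block, 0.0030 with DESeq2 size factors, 0.0595 with library size only, 0.0626 with no filter, 0.0061 with DESeq2, 0.19 with DESeq2 and the block, and 0.31 with quality weights. Pgr (0.57) was -0.32 with limma-voom, -0.27 with quality weights and -0.99 with the replicate block without replicate 1. Over the leave-out fits Elf5 ranged from -0.73 to 2.12, Pgr from -0.89 to 1.27, Hey1 from -0.45 to 1.02, Gata3 from -1.09 to 0.12 and Foxa1 from -1.41 to 0.22, and the cause was not tested. The depth of GFPneg replicate 1, where 3 counts equal 9.84 CPM, limits what can be said of genes below about that level.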

Other observations

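The high endothelial venule genes, the 2 vascular tests set on them, the test of GFPneg replicate 1 as a whole and the mitotic test were chosen after the values were seen; the thinning tests, the capillary genes and the splits of the libraries were set before their results were.

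Several genes of high endothelial venules, the lymph node vessels through which lymphocytes enter, were among those higher in GFPpos cells. Of 21 textbook markers, listed after many of their values had been seen and not tested as a list, 20 were measured, 18 had positive fold changes (median log2 2.67), and 3 rose in edgeR's test (Madcam1, Chst4 and Ccl21a), 11 with the replicate block and 15 without GFPneg replicate 1. The fucosyltransferase gene Fut7 was at 34.8, 36.5 and 84.8 CPM in GFPpos replicates 1, 2 and 3 and at 13.1, 0.565 and 0.820 CPM in GFPneg ones, and Ubd at 306, 244 and 441 against 302, 1.44 and 6.10 CPM. In replicate 1 the median log2 ratio of these genes was 0.06, against 3.81 and 4.79 in replicates 2 and 3, so that the difference in this median rested on replicates 2 and 3. The 3 genes that edgeR called were higher in GFPpos cells in replicate 1 too (Ccl21a 277 against 13.1, Chst4 55.2 against 3.28 and Madcam1 10.9 against 0 CPM, the GFPneg values from 4, 1 and 0 counts). The 2 replicate 1 libraries held like levels of several of them.

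More endothelial cells of unchanged makeup would raise all endothelial markers alike. In replicates 2 and 3 the median of the 19 markers was -0.45 and 1.04, at least 3.75 log2 units below that of the venule genes. The gap exceeded the SD over the markers (1.09 in each). The venule genes were listed after many of their values had been seen, which favours such a gap, so that it does not decide the question. The markers, fixed before the data were examined, did not rise in the median in replicate 2. In replicate 1 the gap was 0.57 against an SD of 2.26. More endothelial cells of unchanged makeup cannot be told apart there, since the markers spread by more than the gap. A candidate explanation is another kind of endothelial cell in GFPpos cells. Of 17 capillary and arterial genes picked before their values were seen, although other capillary genes had been seen to be lower, 15 were measured and 11 had negative fold changes, 0 of them past edgeR's threshold with the 6 libraries, with the block or without GFPneg replicate 1, with a mean over pairs of -0.75 (SD 0.66, n = 3) and pair medians of -0.89, -1.32 and -0.03, so that replicate 3 showed next to no difference. A list of 22 such genes written first, most of them already seen, was set aside for the test and gave -1.17. The venule genes were 1.12 log2 units higher in GFPpos replicate 3 than in the other GFPpos libraries, against 1.39 for the endothelial markers, 1.15 for the pericyte markers and -0.50 for the basal genes. They went with the endothelial markers rather than the basal genes, as the test set on them asked, but the pericyte markers did so as much. This is 1 library and does not single out endothelial cells, so that whether endothelial, pericyte or basal cells carried the venule transcripts stays open, and no sort gate against endothelial cells is given in the sources used here.

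Few genes were called with the 6 libraries. The tables argue against low depth alone as what sets GFPneg replicate 1 apart. GFPneg replicate 2 thinned to the same number of counts correlated with GFPneg replicate 3 at 0.804 (0.799 to 0.807 over 20 draws), and GFPneg replicate 1 at 0.620. At that number of counts 6955 of 13868 genes had a count in GFPneg replicate 1, and 11591 on average in thinned GFPneg replicate 2. With GFPneg replicate 1 left out and GFPneg replicate 2 thinned, a median of 148.5 genes was called (119 to 182). Thinning thus did not bring the calls down to the 9 of the 6 libraries. The same libraries unthinned gave 92 calls, and why thinning raised them was not tested, so that it does not measure lost power. Leaving out GFPneg replicate 1 as a whole gave 92 calls, against 3 to 19 without any other library, and what sets this library apart may be RNA quality or cell makeup, which was not tested.

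The direction of the mitotic genes did not rest on GFPneg replicate 1, since 29 of 30 were higher in GFPpos cells in both other pairs. These genes moved together (estimated correlation 0.701), so that they are not 29 separate observations. Without GFPneg replicate 1, edgeR called 0 of the 30 over all genes. Whether the mitotic transcripts come from basal cells or from other cells of the sort was not tested.

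The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 8 higher genes and 1 lower gene, and the highest other split 0 in either direction. It gave 5 lists up and 8 down, and the highest other split 6 in 1 direction, so that 2 splits reached the number of lists up and 1 the number down. The 3 other splits that part all 3 pairs, by swapping the fractions of 1 pair, called 0 genes. One of them gave the 6 lists.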
